A study of Mus musculus with 14 samples.

How the data were processed

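Polyadenylated RNA from 14 mouse samples was sequenced. 8 samples were fat: brown adipose tissue (BAT), the fat that burns fuel to make heat, and white adipose tissue (WAT) from the perigonadal depot, which stores fat, 4 samples of each. The labels describe C57BL/6N mice aged 22 weeks that had eaten a diet with 60% of its calories from fat for 14 weeks. The other 6 samples were a BAT cell line, differentiated to fat cells in culture, that received either DMSO (vehicle) or 100 µM blebbistatin, an inhibitor of class II myosin motors, for 24 h from day 7 of differentiation, 3 samples of each. The labels number the replicates but do not say that each came from a separate animal or culture. The p-values of single genes below therefore measure the spread between these samples, which may in part be technical. Those of camera and of Fisher's exact test compare genes with other genes and are no measure of that spread. Per the labels' protocols, RNA was extracted with TRIzol and made into libraries with a kit that keeps the strand.

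Per the submitters' processing notes, STAR, HOMER and edgeR were used with genome build mm9, and their versions are not given in the sources used here. Per the file headers, HOMER counted reads in exons with 1 row per gene, for 24421 rows, and each gene symbol has a single row. For each experiment the authors deposited a table of gene signal, which holds read counts scaled by 1 factor per library to a common total. From the deposited signal the worth of a single read was found for each library, and every value of up to 1000 reads came out within 0.1 of a whole read (100% of values), so the read counts could be recovered. The same deposited tables hold the authors' log2 fold changes (BAT over WAT, blebbistatin over vehicle) and the authors' edgeR p-values. A second pair of deposited tables holds RPKM (reads scaled for exon length and for the mapped reads of the library) and exon lengths. The recovered reads and the deposited RPKM together give the number of mapped reads behind each library, an inferred value: it counts all mapped reads, inside and outside the annotated exons. A deposited sheet of 5 myosin genes repeats the tissue RPKM values and was not used. The header of the cell RPKM table names 3 further libraries that were not analysed here.

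Read counts were expected when the tests were planned, with edgeR's quasi-likelihood test as the main test. Since the deposited values are scaled counts, the main test became limma's empirical Bayes test with a mean-variance trend and robust variances, on log2(CPM + 0.5). CPM is the scaled count relative to the library's gene total after TMM normalisation, so a log2 fold change understates the change of a gene with few reads. Genes entered by edgeR's filterByExpr on the recovered reads, with a minimum count of 10 and a minimum total of 15. P-values were adjusted by the Benjamini-Hochberg method and genes under 0.05 were called. The written plan named limma on log2(RPKM + 0.1) as the substitute if the tables held no counts, so using the scaled counts departs from it. RPKM was made an alternative because the share of mapped reads that fell in genes differed between the tissues, which shifted the median gene by -1.53 on the log2 scale. This choice, and the pseudocount, were made after the library totals, that shift, the deposited sheet of myosin RPKM, and the values of Ucp1 and Rn45s in the cells had been seen, and before any gene was tested. Results on RPKM are given for the numbers of called genes and beside some of the main results, mainly where a direction or call changed. Unless said to be centred on library medians, RPKM values for the tissues carry the shift of -1.53 in the median gene. Fits used group as the only term and only the libraries of their own experiment. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.

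For the set tests, 33 gene lists with 661 genes had been written before the data were examined, with the title and design of the series and the topic of the published study (myosin, YAP/TAZ and brown fat) in mind, so they are not blind to its question, covering pathways, actomyosin genes and markers of cell types that the samples could hold. Only 1 gene found no row. Lists with at least 5 tested members were tested with camera, which compares the members with all other genes at a preset correlation between genes of 0.01. Alternatives were camera with an estimated correlation, and fry. Fry's directional test asks whether the genes of a set move, on balance, one way, and its mixed test whether they change in either direction. Counts of called members were also taken with p-values adjusted over the list alone. Genes called between the tissues with an absolute log2 fold change of at least 1 formed a BAT-high and a WAT-high set, which were tested in the cells with camera and Fisher's exact test.

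The rule for naming genes was fixed at the same time. In each comparison it takes the 6 largest rises and 6 largest falls among called genes whose libraries do not overlap between groups and whose mean is at least 10 CPM in the higher group. It adds a panel (Ucp1, Cidea, Ppargc1a, Prdm16, Dio2, Adipoq, Fabp4, Lep, Myh7, Myh9, Yap1, Wwtr1, Ctgf and Cyr61), and for each list the 2 called members with the largest change in the majority direction and the 1 in the other direction, at 1 CPM or more. Genes outside the rule are Krt7, Ptx3, Rn45s and, among the flagged values, Myh10, Myh11 and Myh13, all named after their values were seen. Coordinates are those of the deposited RPKM table in mm9. A span runs from the start to the end of the transcript kept and holds all of its exons and introns, and whether starts are counted from 0 or 1 is not given in the sources used here. Whether HOMER used the strand is likewise not given, so genes that overlap another row are uncertain. In the tissue comparison 17 of the 97 named genes overlap another row and in the cells 7 of 37. Those whose partner had at least 10 CPM on average, a limit set afterwards to keep this account short, are Atp2a1 (Rabep2), Cidea (B430212C06Rik), Ckm (A930016O22Rik), Cpt1b (the read-through row ChkbCpt1b), Mest (Copg2), Myh7 (Mhrt), Plin4 (Hdgfrp2), Prdm16 (5930403L14Rik, in both comparisons) and, in the cells, Tagln (Pcsk7). Reads of close relatives such as the muscle myosins, the actins, or Scd2 and Scd3 can also be exchanged between rows.

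The scripts were tested on simulated reads drawn for the real genes, libraries and depths, with 200 genes changed. For the tissue comparison, over 12736 genes, 67% of 2-fold changes and 94.9% of 4-fold changes were recovered with 12 false calls (6.98% of calls). For the cells, over 12830 genes, recovery was 74.7% and 96.9%, with 9 false calls (5.08%). The reads were recovered exactly in 100% of simulated values. In both comparisons a list of 20 genes moved 2-fold was called, and 0 of 20 unmoved lists were. The simulated genes varied independently of each other, so this does not test camera on lists whose genes move together. With 200 genes changed, it also does not cover a comparison in which 7991 genes are called. Where a group held 0 reads of a gene, the fold is a lower bound against 3 reads over the whole group, and with 1 to 3 reads the ratio is given with its 95% counting interval. Both cover counting error only. Pairs of libraries of the same group differed by more than sampling noise (chi-square per degree of freedom from 5.07 to 49.1 over the 4 groups), so no library was counted as a duplicate. Other settings chosen before testing were other normalisation factors, no filter on genes, DESeq2, edgeR's quasi-likelihood test with other factors, the replicate number as a block, RPKM, a fold limit and leaving out each library. Added after seeing the data were the quasi-likelihood test with TMM on recovered reads, no TMM, other pseudocounts and RPKM centred on library medians. Also added were thinning of reads, removal of 2 ribosomal rows, gene lists without a filter, and the cells without a pair of libraries that stand apart. The quasi-likelihood test with TMM had been planned as the main test and became an alternative.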

Results

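In brown fat, the genes of heat production, respiration and fat burning stood far above their levels in white fat. White fat carried more transcripts of matrix, macrophage and cell cycle genes. In the cultured brown fat cells, Acta2 and Tagln were among the genes that fell with 24 h of blebbistatin. The sequencing behind the tissues was uneven. WAT libraries held 6859404 to 16091370 reads in genes and BAT libraries 1014959 to 2335058. Of the mapped reads implied by the deposited values, 71.1% to 83.0% fell in genes in WAT and 19.1% to 42.3% in BAT (exact permutation test, two-sided, p = 0.0286, the smallest that 70 splits allow). Vehicle libraries held 10685378 to 14176846 reads and blebbistatin libraries 10920307 to 12978198. Across genes, whose values are not independent replicates, libraries of 1 tissue correlated at 0.918 to 0.988 and libraries of different tissues at 0.631 to 0.756. In the cells the correlations were 0.977 to 0.994 within groups and 0.967 to 0.986 between them. The ribosomal precursor Rn45s took 3.45% of the gene reads of vehicle 1 and at most 1.03% in the other cell libraries.

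Ucp1, the uncoupling protein that lets brown fat mitochondria release energy as heat, had the largest rise from WAT to BAT on the log2(CPM + 0.5) scale (n = 4 each; 0.692 ± 0.631 to 15276 ± 3413 CPM, log2 13.76, SE 0.30, adjusted p = 3.06e-11). Cidea, a lipid droplet protein abundant in brown fat, rose as well (2.65 ± 0.586 to 2685 ± 649 CPM, log2 9.72, SE 0.19, adjusted p = 7.54e-12). So did Fabp3, a carrier of fatty acids (1.47 ± 0.512 to 1477 ± 522 CPM, log2 9.53, SE 0.25, adjusted p = 6.88e-11). Dio2, which activates thyroid hormone, rose (2.32 ± 0.916 to 121 ± 40.5 CPM, log2 5.41, SE 0.28, adjusted p = 1.40e-08). Ppargc1a, a coactivator that drives mitochondrial genes, rose (3.39 ± 1.48 to 72.0 ± 8.67 CPM, log2 4.30, SE 0.26, adjusted p = 4.52e-08). Prdm16, a regulator of brown fat identity, rose too (5.26 ± 1.83 to 36.5 ± 15.5 CPM, log2 2.63, SE 0.33, adjusted p = 2.04e-05). All 25 tested genes of the thermogenic program rose (median log2 4.75, adjusted p = 3.05e-17, and adjusted p = 0.0552 with an estimated correlation). Ucp1 (NM_009463) spans 85814247 to 85822355 on the plus strand of chromosome 8. Cidea (NM_007702) spans 67503218 to 67527448 on the plus strand of chromosome 18.

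Genes of the mitochondrial fuel pathways rose with them. Of 75 genes of the respiratory chain and ATP synthase, 73 rose and 2 were not called (median log2 2.99, adjusted p = 2.78e-32, and adjusted p = 0.0552 with an estimated correlation). Uqcrfs1, a subunit of complex III, was among them (log2 4.03, SE 0.23, adjusted p = 2.45e-08). Cyc1, another, rose by as much (log2 4.03, SE 0.20, adjusted p = 1.22e-08). All 18 genes of the tricarboxylic acid cycle rose (median log2 3.14, adjusted p = 1.47e-12, and adjusted p = 0.282 with an estimated correlation), such as Suclg1 (log2 4.12, SE 0.23, adjusted p = 2.57e-08) and Idh3a (log2 3.91, SE 0.19, adjusted p = 1.01e-08). In fatty acid oxidation 20 of 21 rose and 1 fell (median log2 3.18, adjusted p = 2.48e-10, and adjusted p = 0.282 with an estimated correlation). Cpt1b, the muscle form of the enzyme that admits fatty acids to mitochondria, went from 7.50 ± 2.52 to 1327 ± 140 CPM, log2 7.42, SE 0.19, adjusted p = 5.09e-11. Acadvl, which starts the oxidation of long chains, rose (log2 4.44, SE 0.18, adjusted p = 2.84e-09). Cpt1a, the liver form of the same entry enzyme, fell (257 ± 7.87 to 63.3 ± 5.76 CPM, log2 -2.02, SE 0.12, adjusted p = 3.78e-08). Cpt1b shares its span with a read-through row that takes part of the same reads.

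**Figure D1:**
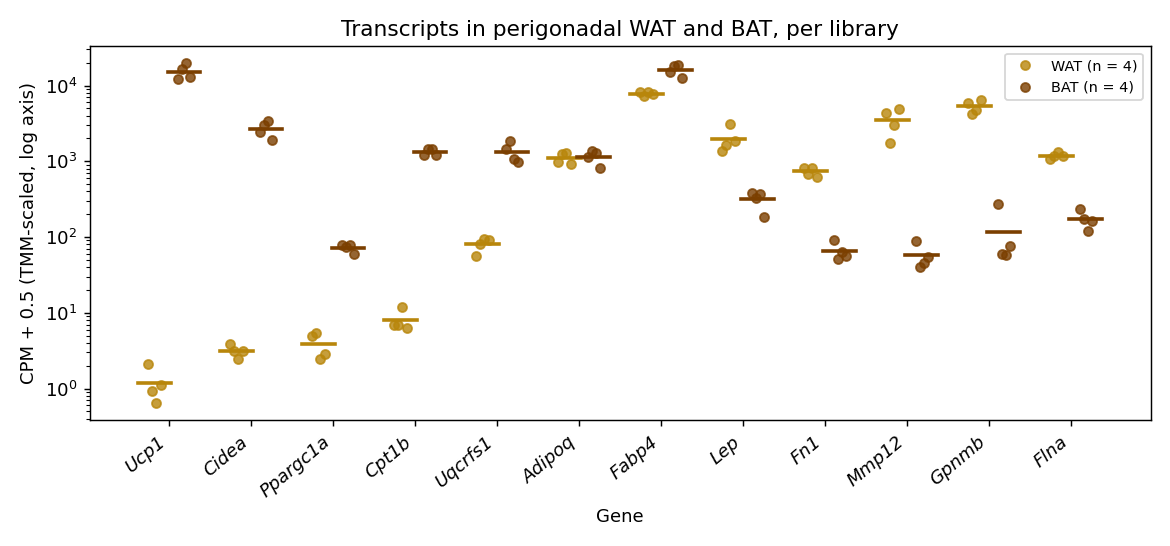
CPM + 0.5 (log axis) of 12 genes in the 4 WAT and 4 BAT libraries, with dots for libraries and bars for group means. Ucp1 averages 0.692 CPM in WAT and 15276 CPM in BAT, Adipoq 1107 and 1146.

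Genes for making and storing fat moved in both directions. In fatty acid and triglyceride synthesis 16 of 20 rose, 2 fell and 2 were not called (median log2 1.72, adjusted p = 2.40e-06, and adjusted p = 0.294 with an estimated correlation). On RPKM the median of this list was 0.24, and 1.81 once RPKM was centred on library medians. Elovl6, which lengthens fatty acids, rose (log2 5.35, SE 0.21, adjusted p = 1.93e-09). Mlxipl, a sugar-sensing transcription factor, rose as well (log2 4.01, SE 0.21, adjusted p = 1.48e-08). Scd2, a desaturase, fell (log2 -0.77, SE 0.25, adjusted p = 0.0177). The call was lost without WAT 3 (log2 -0.54, adjusted p = 0.0502), BAT 3 (log2 -0.61, adjusted p = 0.0686) or BAT 4 (log2 -0.70, adjusted p = 0.0553). Of 20 shared adipocyte genes, 13 rose, 3 fell and 4 were not called (median log2 0.80, adjusted p = 0.00815, and adjusted p = 0.397 with an estimated correlation). On deposited RPKM the median was -0.69, and 0.88 once centred on library medians. Slc2a4, the insulin-regulated glucose transporter, and Gpd1, which supplies glycerol phosphate, rose (log2 3.72, SE 0.24, adjusted p = 6.47e-08; log2 3.19, SE 0.25, adjusted p = 3.22e-07). The lipid droplet protein Plin4 fell (log2 -0.99, SE 0.17, adjusted p = 2.74e-04). Fabp4, a fatty acid carrier of all fat cells, rose (7850 ± 486 to 16153 ± 2825 CPM, log2 1.03, SE 0.18, adjusted p = 3.57e-04; log2 -0.46 on RPKM). Adipoq, the hormone adiponectin, was not called (1107 ± 184 to 1146 ± 240 CPM, log2 0.04, SE 0.19, adjusted p = 0.872). Its sign turned without WAT 1, WAT 4, BAT 2 or BAT 3 (log2 -0.02, -0.04, -0.06 and -0.02), and on RPKM it was called lower (log2 -1.45, adjusted p = 9.52e-04).

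All 13 tested white adipose markers fell (median log2 -2.38, adjusted p = 2.14e-05, and adjusted p = 0.0552 with an estimated correlation). Lep, the satiety hormone leptin, went from 1990 ± 770 to 314 ± 90.9 CPM, log2 -2.65, SE 0.28, adjusted p = 4.60e-06. Mest and Agt fell too (log2 -4.41, SE 0.26, adjusted p = 3.83e-08; log2 -3.67, SE 0.40, adjusted p = 6.34e-06). In glycolysis 16 of 19 rose, 2 fell and 1 was not called (median log2 1.64, adjusted p = 9.27e-06, and adjusted p = 0.0763 with an estimated correlation). On RPKM the glycolysis median was 0.16, and 1.73 once centred on library medians. Ldhb, a lactate dehydrogenase, rose (log2 5.32, SE 0.17, adjusted p = 4.90e-10). Eno3, the muscle enolase, rose (log2 4.71, SE 0.76, adjusted p = 4.04e-04; log2 3.85 without BAT 4 and 5.30 without BAT 3). Aldoc, an aldolase of brain, fell (log2 -1.35, SE 0.55, adjusted p = 0.0489). It passed in only 7 of 21 alternatives, among the losses DESeq2, edgeR's quasi-likelihood test and the fit without a filter (adjusted p = 0.181, 0.161 and 0.0526), and the authors' table gives adjusted p = 0.0958. The gene went untested whichever WAT library was left out, and its call was lost without BAT 2, BAT 3 or BAT 4 (log2 -0.87, -1.41 and -1.26, adjusted p = 0.119, 0.0579 and 0.0874). In cholesterol synthesis 13 of 19 fell and 6 were not called (median log2 -1.08, adjusted p = 0.00815, and adjusted p = 0.302 with an estimated correlation). Msmo1 fell (log2 -1.89, SE 0.19, adjusted p = 2.73e-06), and so did Hsd17b7 (log2 -2.14, SE 0.68, adjusted p = 0.0175; log2 -1.28 without BAT 3). Of 21 genes of beta-adrenergic signalling and calcium handling, 13 rose, 6 fell and 2 were not called (median log2 0.91, adjusted p = 0.0211, and adjusted p = 0.294 with an estimated correlation). Their median was -0.54 on RPKM and 1.03 once centred on library medians. Gnas, the stimulatory G protein, and Pde4d, which breaks down cyclic AMP, rose (log2 3.19, SE 0.20, adjusted p = 5.54e-08; log2 3.04, SE 0.20, adjusted p = 8.14e-08). The calcium channel Trpv2 fell (log2 -3.35, SE 0.26, adjusted p = 2.83e-07). Lep (NM_008493) spans 29010221 to 29023876 on the plus strand of chromosome 6.

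Skeletal muscle transcripts were high in every BAT library and highest in BAT 4. All 28 tested sarcomere genes rose (median log2 6.46, adjusted p = 8.60e-12, and adjusted p = 0.294 with an estimated correlation), and so did 16 of 17 muscle markers outside the sarcomere, with 1 not called (median log2 5.09, adjusted p = 3.46e-06, and adjusted p = 0.302 with an estimated correlation). The summed sarcomere genes came to 2739, 5306, 2841 and 38541 CPM in BAT 1 to 4, against 54.8 to 71.9 CPM in WAT. The muscle markers outside the sarcomere summed to 1386, 2465, 1479 and 16279 CPM in the same BAT libraries. That list and its sum include 1 gene that is also on the sarcomere list. The fast myosin Myh4 went from 0.150 ± 0.135 to 2322 ± 3331 CPM, log2 10.79, SE 0.77, adjusted p = 1.25e-06. The creatine kinase Ckm went from 0.183 ± 0.0340 to 1366 ± 1912 CPM, log2 10.00, SE 0.73, adjusted p = 1.59e-06. The troponin Tnnt3 went from 0.419 ± 0.0927 to 1592 ± 2229 CPM, log2 9.84, SE 0.71, adjusted p = 1.34e-06. Without BAT 4 these came to log2 9.91, 9.14 and 8.99. Atp2a1, the calcium pump of fast fibres, rose too (log2 8.88, SE 0.73, adjusted p = 3.63e-06; 256-fold without BAT 4). Myh4 (NM_010855) spans 67051314 to 67073949 on the plus strand of chromosome 11.

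Among the muscle myosin heavy chains 5 of 6 tested rose and 1 fell (median log2 7.37, adjusted p = 0.0211, and adjusted p = 0.302 with an estimated correlation). Myh7, the slow myosin of heart and slow muscle, rose from 3 reads in all WAT libraries (BAT 187 ± 272 CPM, n = 4 each, log2 7.25, SE 0.83, adjusted p = 2.78e-05, ratio 2489 with a 95% counting interval of 850 to 12090). Its BAT libraries read 17.6, 64.1, 71.7 and 594 CPM, with log2 6.32 without BAT 4 and 7.97 without BAT 1. Myh1 rose (log2 8.43, SE 0.73, adjusted p = 5.10e-06; log2 7.60 without BAT 4) and Myh15, a slow tonic myosin, fell (log2 -4.17, SE 0.48, adjusted p = 9.94e-06). Of 14 myosin heavy chain genes, 9 had a higher mean RPKM in BAT, on a scale whose median gene lies at -1.53, and more did by CPM. Myh9, a nonmuscle myosin and target of blebbistatin, fell (810 ± 63.9 to 248 ± 47.7 CPM, log2 -1.72, SE 0.16, adjusted p = 1.43e-06). Reads of closely related muscle myosins can be exchanged between genes. Myh7 (NM_080728) spans 55589525 to 55613386 on the minus strand of chromosome 14. Myh9 (NM_022410) spans 77591015 to 77672605 on the minus strand of chromosome 15.

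**Figure D2:**
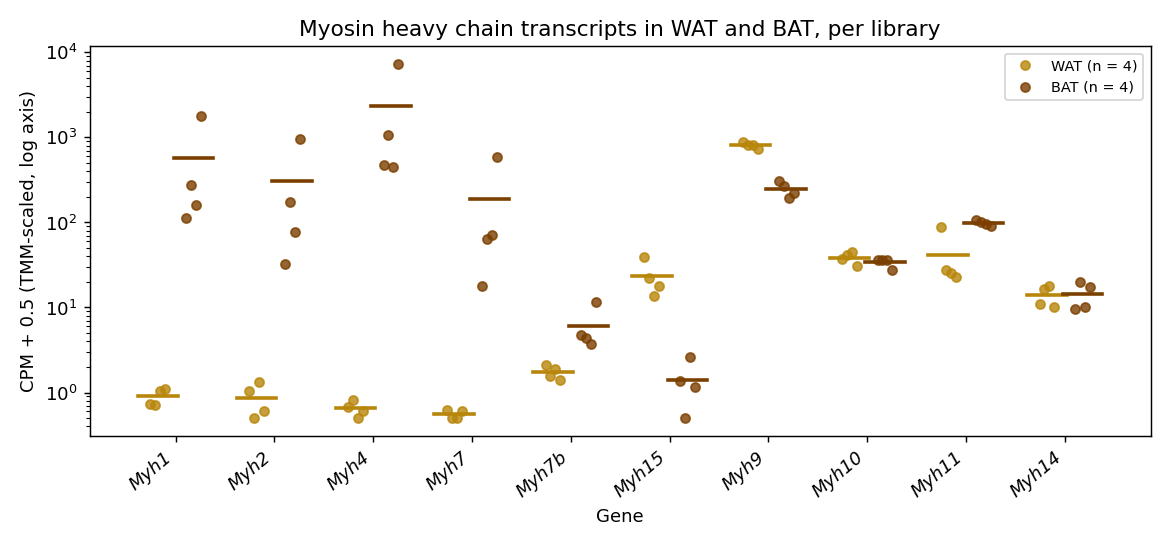
CPM + 0.5 (log axis) of 10 myosin heavy chain genes in the 4 WAT and 4 BAT libraries, with dots for libraries and bars for group means. Myh4 averages 0.150 CPM in WAT and 2322 CPM in BAT, Myh9 810 and 248.

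Matrix and adhesion genes were lower in BAT. Of 27 extracellular matrix genes 26 fell (27 adjusted over the list alone; median log2 -2.01, adjusted p = 1.15e-09, and adjusted p = 0.141 with an estimated correlation). Fn1, fibronectin, went from 736 ± 103 to 64.9 ± 18.2 CPM, log2 -3.52, SE 0.19, adjusted p = 1.65e-08, and Fbn1, fibrillin, fell (log2 -3.12, SE 0.19, adjusted p = 4.21e-08). In focal adhesion 15 of 21 fell, 1 rose and 5 were not called (median log2 -0.87, adjusted p = 4.85e-04, and adjusted p = 0.282 with an estimated correlation). The actin crosslinker Flna fell (1183 ± 109 to 172 ± 47.0 CPM, log2 -2.81, SE 0.19, adjusted p = 9.84e-08), as did the fibronectin receptor Itga5 (log2 -2.54, SE 0.22, adjusted p = 9.49e-07). The adaptor Bcar1 rose (log2 0.55, SE 0.20, adjusted p = 0.0300; log2 -0.89 on RPKM). Its call was lost without WAT 1, WAT 2, WAT 4, BAT 3 or BAT 4 (adjusted p = 0.0535, 0.0706, 0.0878, 0.0588 and 0.0680). Of 24 nonmuscle and smooth muscle actomyosin genes, 5 rose, 13 fell and 6 were not called, and the list was not called (median log2 -0.52, adjusted p = 0.0801). Actg1, a cytoplasmic actin, and Actn1, an actinin, fell (log2 -2.90, SE 0.22, adjusted p = 2.43e-07; log2 -2.80, SE 0.16, adjusted p = 2.92e-08). The tropomyosin Tpm2 rose (log2 4.21, SE 0.73, adjusted p = 6.49e-04, and log2 3.34 without BAT 4). Like the sarcomere genes, it was highest in BAT 4 (2899 CPM, other BAT libraries 216 to 307 CPM). Of 25 targets of MRTF and SRF, transcription factors that answer to actin, 5 rose, 13 fell and 7 were not called (median log2 -0.66, adjusted p = 0.0272, and adjusted p = 0.373 with an estimated correlation). Fn1 (NM_001276411) spans 71632047 to 71699808 on the minus strand of chromosome 1.

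YAP and TAZ are transcription cofactors that respond to mechanical tension. Yap1 rose (49.2 ± 6.10 to 69.7 ± 5.92 CPM, log2 0.50, SE 0.14, adjusted p = 0.00698; log2 -0.95 on RPKM) and Wwtr1, which encodes TAZ, was not called (152 ± 26.4 to 129 ± 9.55 CPM, log2 -0.23, SE 0.14, adjusted p = 0.186). Wwtr1 passed in 6 of 26 alternatives, all downward, on RPKM (log2 -1.69, adjusted p = 1.15e-04), without a filter (0.0365, and 0.0413 in the quasi-likelihood test) and without TMM (0.0334). Of 19 YAP/TAZ targets 2 rose, 8 fell and 9 were not called, and the list was not called (median log2 -0.34, adjusted p = 0.0628; adjusted p = 0.0290 without WAT 1 and 0.0176 without a filter). Ctgf, a matrix signal, fell (log2 -1.06, SE 0.31, adjusted p = 0.0102). Cyr61, its relative, was not called (log2 0.40, SE 0.20, adjusted p = 0.106; log2 0.55, adjusted p = 0.0332 without WAT 2; called lower on RPKM, log2 -1.08, adjusted p = 0.0120). Myof and Axl fell (log2 -4.19, SE 0.24, adjusted p = 2.88e-08; log2 -2.47, SE 0.15, adjusted p = 4.33e-08) and Amotl2 rose (log2 0.88, SE 0.18, adjusted p = 9.76e-04; log2 -0.60 on RPKM). Of 16 pathway components 3 rose, 5 fell (4 adjusted over the list alone) and 8 were not called (median log2 -0.25, adjusted p = 0.519, and median -1.60 on RPKM). Tead1, a DNA-binding partner of YAP, rose (log2 1.00, SE 0.20, adjusted p = 8.75e-04; log2 -0.47 on RPKM). The kinase Stk4 fell (log2 -1.47, SE 0.13, adjusted p = 1.17e-06). Mob1a, another pathway component, fell as well (log2 -3.70, SE 0.87, adjusted p = 0.00411, log2 -2.70 without BAT 3 and -4.29 without BAT 1).

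Markers of other cell types differed between the tissues. All 21 macrophage markers fell in BAT (median log2 -4.10, adjusted p = 8.60e-12, and adjusted p = 0.294 with an estimated correlation). Their sum was 19233 to 26390 CPM in WAT and 881 to 2099 CPM in BAT. Mmp12, a macrophage elastase, went from 3492 ± 1414 to 56.7 ± 22.1 CPM, log2 -5.90, SE 0.32, adjusted p = 2.79e-08. Gpnmb, of lipid-laden macrophages, went from 5316 ± 1023 to 116 ± 104 CPM, log2 -5.83, SE 0.43, adjusted p = 7.01e-07. Of 6 lymphocyte markers 3 fell (2 adjusted over the list alone) and 3 were not called, among the falls Il7r and Cd22 (log2 -4.16, SE 0.22, adjusted p = 1.50e-08; log2 -3.51, SE 0.49, adjusted p = 4.52e-05). That list was not called (median log2 -1.26, adjusted p = 0.0667), though it passed without BAT 1, BAT 2 or BAT 3 (adjusted p = 0.0491, 0.0385 and 0.0254). Endothelial markers were higher in BAT, with 12 of 14 called and 0 lower (median log2 1.68, adjusted p = 3.46e-06, and adjusted p = 0.172 with an estimated correlation). Their median was 0.22 on RPKM, and 1.79 once centred on library medians. Emcn and Egfl7 were among the rises (log2 2.64, SE 0.21, adjusted p = 4.73e-07; log2 2.43, SE 0.17, adjusted p = 1.29e-07). Of 14 fibroblast and preadipocyte markers 3 rose, 7 fell (10 adjusted over the list alone) and 4 were not called (median log2 -0.66, adjusted p = 0.121). Mfap5 and Col14a1 fell (log2 -2.58, SE 0.19, adjusted p = 2.22e-07; log2 -2.49, SE 0.21, adjusted p = 7.39e-07). Dlk1 rose (log2 3.59, SE 0.38, adjusted p = 4.41e-06). All 7 mesothelial markers fell (median log2 -3.59, adjusted p = 0.00446, and adjusted p = 0.294 with an estimated correlation). Upk3b and Msln had 0 reads in BAT, which puts them at least 27.6-fold and 16.4-fold lower, and Msln was left untested without WAT 2, WAT 3 or WAT 4. Mmp12 (NM_008605) spans 7347374 to 7360461 on the plus strand of chromosome 9.

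Cell cycle genes fell, 23 of 24 with 1 not called (median log2 -1.88, adjusted p = 2.12e-05, and adjusted p = 0.294 with an estimated correlation). Among them were the replication helicase subunit Mcm3 and the mitotic kinase Cdk1 (log2 -2.60, SE 0.38, adjusted p = 7.97e-05; log2 -2.48, SE 0.42, adjusted p = 2.61e-04). In the unfolded protein response 13 of 15 fell, 1 rose and 1 was not called (median log2 -0.93, adjusted p = 0.00277, and adjusted p = 0.294 with an estimated correlation). Sdf2l1 and Edem1 fell (log2 -2.53, SE 0.27, adjusted p = 5.31e-06; log2 -1.44, SE 0.16, adjusted p = 7.11e-06) and Herpud1 rose (log2 1.54, SE 0.12, adjusted p = 2.97e-07; log2 0.07 on RPKM). Of 13 inflammatory cytokines and NF-kB targets 1 rose, 8 fell (9 adjusted over the list alone) and 4 were not called (median log2 -1.30, adjusted p = 0.0246, and adjusted p = 0.294 with an estimated correlation). Il1rn, the antagonist of interleukin 1, and Saa3, an acute phase protein, fell (log2 -3.76, SE 0.33, adjusted p = 1.20e-06; log2 -3.22, SE 0.64, adjusted p = 0.00111, log2 -2.62 without WAT 2). The NF-kB inhibitor Nfkbia rose (log2 1.12, SE 0.15, adjusted p = 4.17e-05; log2 -0.37 on RPKM). On the log2(CPM + 0.5) scale, which shortens the falls of genes with few reads such as Upk3b, Col6a5, a collagen, fell most among genes of at least 10 CPM (190 ± 76.1 to 1.35 ± 1.27 CPM, log2 -6.82, SE 0.41, adjusted p = 4.95e-08). Next on that scale were Oxtr, the oxytocin receptor (log2 -6.20, SE 0.57, adjusted p = 3.48e-06), and Gpr50 (2 reads in BAT, log2 -6.10, SE 0.47, adjusted p = 2.86e-07, ratio 155 with a 95% counting interval of 43.0 to 1285). Pik3ap1 (log2 -6.08, SE 0.42, adjusted p = 1.41e-07) and Mmp12 were also among the largest falls.

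In total 7991 of 12754 tested genes differed between the tissues at an adjusted p under 0.05 in limma's test, 3745 higher and 4246 lower in BAT. Of these 2349 and 2640 changed by at least 2-fold. On the deposited RPKM, the written substitute, the split was 773 higher and 9586 lower, on a scale whose median gene lies at -1.53. With edgeR's quasi-likelihood test on the recovered reads, 8092 genes were called. The authors' table calls 8853 genes (4000 higher, 4853 lower), of which 7283 are called here. Leaving out any 1 library gave 7004 to 8442 calls, and 6607 held in all 8 such fits. Of 32 tested lists 22 were called, 12 up and 10 down, and 0 with an estimated correlation (lowest adjusted p = 0.0552). Without a filter, chosen for the lists after seeing the data, 28 were called. The 6 gained were actomyosin, YAP/TAZ targets, and the fibroblast, Schwann, NRF2 and lymphocyte lists (adjusted p = 0.0156, 0.0176, 0.0499, 0.0163, 0.0499 and 0.0257). Fry called 29 in 1 direction and 32 in its mixed test. Library names in the file headers begin differently for the tissues, so any batch between them cannot be told apart from tissue.

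**Figure D3:**
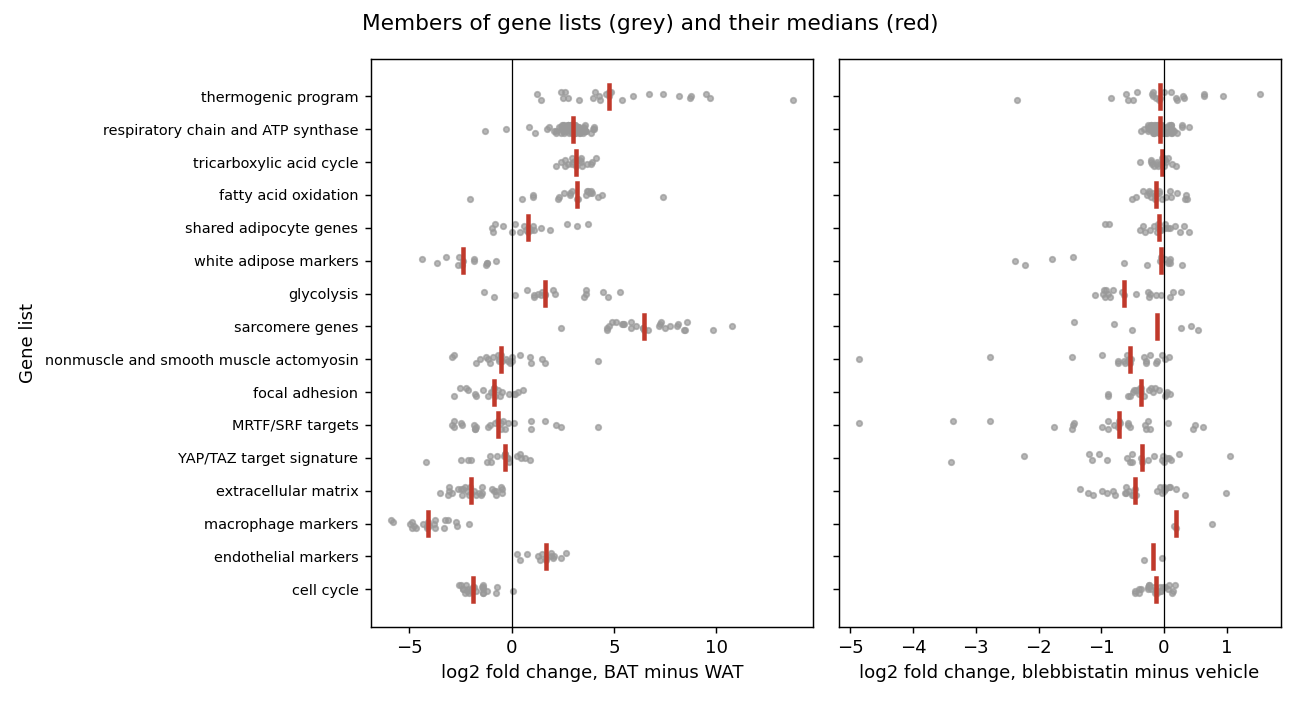
Log2 fold change of the members of 16 lists (grey) with list medians (red), BAT over WAT and blebbistatin over vehicle. The thermogenic program has a median of 4.75 in the tissues and -0.07 in the cells.

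In the brown fat cells under blebbistatin, Acta2, smooth muscle actin, had the largest fall on the log2(CPM + 0.5) scale among genes of at least 10 CPM (n = 3 each; 271 ± 64.1 to 8.65 ± 0.978 CPM, log2 -4.86, SE 0.19, adjusted p = 5.95e-05). It was followed by Ankrd1, a muscle ankyrin and YAP target (log2 -3.40, SE 0.28, adjusted p = 0.00287), and Tagln, an actin-binding protein of smooth muscle (94.8 ± 23.7 to 8.65 ± 1.64 CPM, log2 -3.36, SE 0.22, adjusted p = 0.00123). Myl9, a myosin light chain, and Ctgf fell as well (87.8 ± 28.8 to 12.1 ± 2.53 CPM, log2 -2.77, SE 0.25, adjusted p = 0.00447; 104 ± 22.7 to 21.4 ± 1.28 CPM, log2 -2.24, SE 0.17, adjusted p = 0.00233). These 5 stayed called whichever library was left out. Acta2 (NM_007392) spans 34314826 to 34329863 on the minus strand of chromosome 19. Ankrd1 (NM_013468) spans 36186455 to 36194334 on the minus strand of chromosome 19. Tagln (NM_011526) spans 45737711 to 45744141 on the minus strand of chromosome 9.

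Of 25 MRTF/SRF targets 7 fell and 18 were not called (1 rose and 16 fell adjusted over the list alone; median log2 -0.71, adjusted p = 9.24e-16, and adjusted p = 0.282 with an estimated correlation). Of 22 nonmuscle and smooth muscle actomyosin genes 5 fell and 17 were not called (14 fell adjusted over the list alone; median log2 -0.54, adjusted p = 5.62e-15, and adjusted p = 0.282 with an estimated correlation). Myh9 was not called (1423 ± 154 to 979 ± 72.1 CPM, log2 -0.54, SE 0.13, adjusted p = 0.130). It passed in 2 of 25 alternatives, DESeq2 (log2 -0.54, adjusted p = 0.00285) and the fit without vehicle 1 and blebbistatin 3 (log2 -0.67, adjusted p = 0.00645), and the authors' table calls it lower (log2 -0.54, adjusted p = 0.0291). Myh7 had 1 read in each group. In focal adhesion 0 of 21 were called (8 fell adjusted over the list alone; median log2 -0.36, adjusted p = 8.12e-07, and adjusted p = 0.282 with an estimated correlation). Of 22 YAP/TAZ targets 3 fell and 19 were not called (1 rose and 6 fell adjusted over the list alone; median log2 -0.36, adjusted p = 3.09e-05, and adjusted p = 0.388 with an estimated correlation). The YAP/TAZ targets summed to 2077 CPM in vehicle 1, near the 1885 to 2025 CPM under blebbistatin, and to 2705 and 3092 CPM in vehicle 2 and 3. Cyr61 was not called (250 ± 86.7 to 116 ± 3.96 CPM, log2 -1.04, SE 0.25, adjusted p = 0.126), but was without vehicle 1 (log2 -1.36, adjusted p = 9.20e-04), without vehicle 1 and blebbistatin 3 (3.39e-05) and with DESeq2 (7.87e-04). Among 16 pathway components 0 were called (median log2 -0.05, adjusted p = 0.627; median 0.02 without TMM). Yap1 and Wwtr1 stood at log2 -0.08 and 0.17 (adjusted p = 0.880 and 0.663). Of 27 extracellular matrix genes 1 fell, Timp1, an inhibitor of matrix proteases (log2 -0.82, SE 0.14, adjusted p = 0.0459). Its call was lost without vehicle 2, vehicle 3, blebbistatin 1 or blebbistatin 2 (adjusted p = 0.230, 0.129, 0.176 and 0.187). Another 26 were not called (2 rose and 11 fell adjusted over the list alone; median log2 -0.46, adjusted p = 2.18e-05, and adjusted p = 0.406 with an estimated correlation). Their sum in vehicle 1 (31987 CPM) lay within the range under blebbistatin (30761 to 32479 CPM), below vehicle 2 and 3 (43699 and 49174 CPM).

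**Figure D4:**
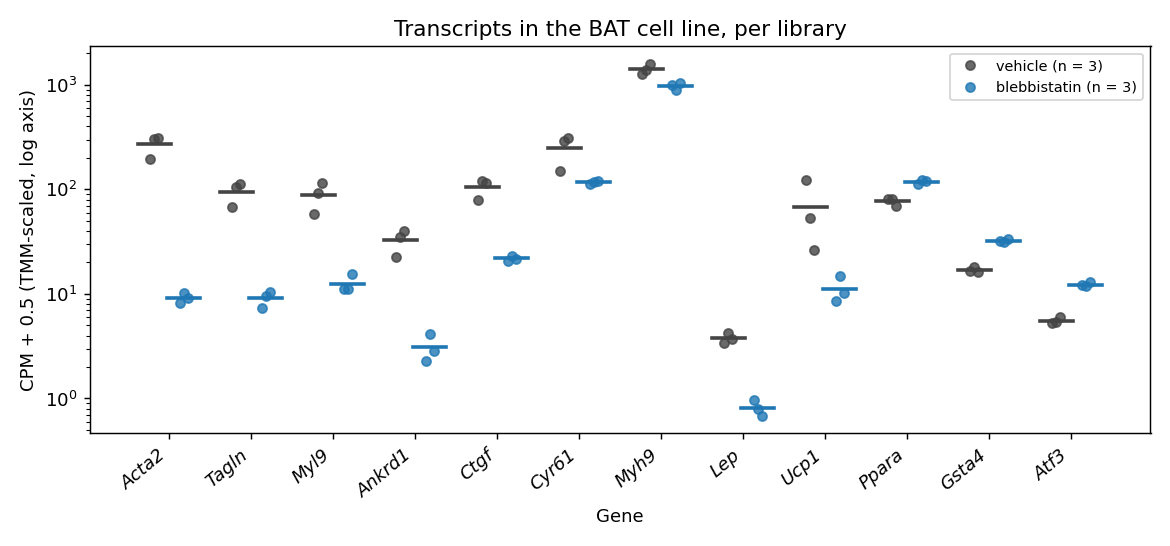
CPM + 0.5 (log axis) of 12 genes in the 3 vehicle and 3 blebbistatin libraries of the cell line, with dots for libraries and bars for group means. Acta2 averages 271 CPM with vehicle and 8.65 CPM with blebbistatin.

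Ucp1 had a lower mean under blebbistatin that did not pass the test (67.3 ± 50.2 to 10.7 ± 3.17 CPM, log2 -2.35, SE 0.49, adjusted p = 0.0908; 0.0148 adjusted over the list alone). Its vehicle libraries read 123, 52.6 and 26.1 CPM and its blebbistatin libraries 8.15, 14.3 and 9.82 CPM. It was called without vehicle 1 (log2 -1.78, adjusted p = 0.0321), without vehicle 3 (log2 -2.89, adjusted p = 0.0393) and with DESeq2 (log2 -2.65, adjusted p = 0.00389). The authors' table gives log2 -2.64 and adjusted p = 1.89e-07. Across 25 alternatives, 4 pass the threshold. Of 22 thermogenic genes 1 rose and 21 were not called (2 rose and 1 fell adjusted over the list alone), and the list was not called (median log2 -0.07, adjusted p = 0.792, where the test points up; 0.14 on RPKM). Ppara, a regulator of fat burning, rose (76.2 ± 6.48 to 118 ± 5.48 CPM, log2 0.63, SE 0.10, adjusted p = 0.0441). Its call was lost whichever library other than vehicle 1 was left out (adjusted p = 0.220 without vehicle 2). Not called were Ppargc1a (log2 0.94, SE 0.30, adjusted p = 0.246), Cidea (log2 0.32, SE 0.23, adjusted p = 0.662), Prdm16 (log2 -0.43, SE 0.19, adjusted p = 0.422), Dio2 (log2 -0.57, SE 0.27, adjusted p = 0.454), Adipoq (log2 -0.31, SE 0.15, adjusted p = 0.474) and Fabp4 (log2 -0.17, SE 0.27, adjusted p = 0.869). Ppargc1a passed in 1 of 25 alternatives, without vehicle 1 and blebbistatin 3 (log2 0.85, adjusted p = 0.0184), and the authors' table calls it higher (log2 0.99, adjusted p = 0.0475). Ppara (NM_001113418) spans 85565994 to 85637281 on the plus strand of chromosome 15.

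Lep fell (3.28 ± 0.394 to 0.317 ± 0.141 CPM, log2 -2.22, SE 0.23, adjusted p = 0.00741), a call lost without vehicle 2 (adjusted p = 0.0773). Npr3, a clearance receptor for natriuretic peptides, also fell (log2 -2.37, SE 0.32, adjusted p = 0.0210; adjusted p = 0.150 without vehicle 2). They were 2 of 3 called among 14 white adipose markers, the others not called (5 fell adjusted over the list alone; median log2 -0.05, adjusted p = 0.00211, and adjusted p = 0.282 with an estimated correlation; mean -0.59; median 0.01 without TMM). In glycolysis 0 of 19 were called (9 fell adjusted over the list alone; median log2 -0.64, adjusted p = 4.50e-05, and adjusted p = 0.355 with an estimated correlation). The glycolysis genes summed to 10828, 6637 and 5277 CPM in vehicle 1, 2 and 3, against 4580 to 4816 CPM under blebbistatin, and their median level in vehicle 3 (133 CPM) was that of the blebbistatin libraries (130 to 133 CPM). In the next 5 lists 0 members were called, and the lists were not called. The respiratory chain stood at median log2 -0.07, adjusted p = 0.0928 (2.92e-04 without vehicle 3 and 3.33e-04 without blebbistatin 2) and the tricarboxylic acid cycle at median log2 -0.04, adjusted p = 0.298 (0.00508 and 0.0440 without the same libraries). Fatty acid oxidation stood at median log2 -0.13, adjusted p = 0.362 (0.0293 and 0.00793) and the shared adipocyte genes at median log2 -0.07, adjusted p = 0.300 (0.00430 and 0.0425). Fatty acid and triglyceride synthesis stood at median log2 0.08, adjusted p = 0.443 (0.00145 without vehicle 1 and 0.0188 without blebbistatin 1). Cholesterol synthesis was called upward with 0 of 19 members called (median log2 0.11, adjusted p = 0.00595, and adjusted p = 0.397 with an estimated correlation; 0.115 without blebbistatin 2). Beta-adrenergic and calcium genes were not called, 0 of 19 (1 fell adjusted over the list alone; median log2 -0.02, adjusted p = 0.382; 0.05 without TMM).

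Of 15 inflammatory cytokines and NF-kB targets 3 fell and 12 were not called (5 fell adjusted over the list alone; median log2 -0.40, adjusted p = 3.26e-04, and adjusted p = 0.190 with an estimated correlation). The chemokines Ccl7 and Ccl2 fell (log2 -2.41, SE 0.26, adjusted p = 0.00776; log2 -1.79, SE 0.26, adjusted p = 0.0307; adjusted p = 0.0773 and 0.187 without vehicle 2). NRF2 and aryl hydrocarbon receptor targets were called upward, 1 of 13 rose (5 rose and 1 fell adjusted over the list alone; median log2 0.30, adjusted p = 7.94e-05, and adjusted p = 0.190 with an estimated correlation), the glutathione transferase Gsta4 (log2 0.92, SE 0.11, adjusted p = 0.0175; 0.110 without vehicle 2). The integrated stress response was called upward with 1 of 19 risen (4 adjusted over the list alone; median log2 0.17, adjusted p = 0.0223, and adjusted p = 0.419 with an estimated correlation; 0.118 without vehicle 3 and 0.150 without blebbistatin 1), the stress factor Atf3 (log2 1.15, SE 0.15, adjusted p = 0.0192; 0.150 without vehicle 2). In the unfolded protein response 1 of 15 fell (3 adjusted over the list alone; median log2 -0.19, adjusted p = 0.0196, and adjusted p = 0.323 with an estimated correlation; 0.0562 without vehicle 3 and 0.0691 without blebbistatin 3), Xbp1 (log2 -0.73, SE 0.13, adjusted p = 0.0468; 0.287 without vehicle 2). Interferon genes were called upward with 0 of 15 called (2 rose adjusted over the list alone; median log2 0.14, adjusted p = 0.0169, and adjusted p = 0.492 with an estimated correlation; 0.357 without vehicle 1 and 0.196 without blebbistatin 3). Cell cycle genes were called downward with 0 of 24 called (median log2 -0.13, adjusted p = 0.00588, and adjusted p = 0.355 with an estimated correlation; 0.114 without vehicle 1). The p53 targets were not called, 0 of 16 (median log2 -0.03, adjusted p = 0.176; median 0.03 without TMM).

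Of 12 fibroblast and preadipocyte markers 1 fell, Ly6a (log2 -1.03, SE 0.16, adjusted p = 0.0388; 0.201 without vehicle 2), with 3 fallen adjusted over the list alone (median log2 -0.39, adjusted p = 0.00588, and adjusted p = 0.323 with an estimated correlation). Schwann and nerve markers were called downward with 0 of 5 called (2 fell adjusted over the list alone; median log2 -0.47, adjusted p = 0.0301, and adjusted p = 0.282 with an estimated correlation; 0.0624 without vehicle 1 and 0.113 without blebbistatin 3). Of 6 sarcomere genes 1 fell, Ldb3 (log2 -1.43, SE 0.24, adjusted p = 0.0455; 0.230 without vehicle 2), and the list was not called (median log2 -0.11, adjusted p = 0.459). The 9 muscle markers outside the sarcomere were not called (median log2 -0.26, adjusted p = 0.0912; 0.0448 without vehicle 2 and 0.0430 without vehicle 3). Under 5 members were tested of the muscle myosins (1), macrophage (3, median 0.19), lymphocyte (2, 0.07), endothelial (2, -0.17) and mesothelial markers (3, -1.66), where Krt19, a keratin, fell (log2 -1.66, SE 0.24, adjusted p = 0.0309; 0.147 without vehicle 2; 3 fell adjusted over the list alone), and 0 of the epididymis markers. The largest rises at 10 CPM or more were Scd3, a desaturase whose reads can be exchanged with its relatives (7.54 ± 5.77 to 52.9 ± 22.4 CPM, log2 2.86, SE 0.49, adjusted p = 0.0468), Abcc4, an exporter (log2 1.35, SE 0.18, adjusted p = 0.0215), Sparcl1 (log2 1.18, SE 0.19, adjusted p = 0.0422), Atf3, Prkaa2, a subunit of the energy sensor AMPK (log2 1.12, SE 0.16, adjusted p = 0.0307), and Fa2h (log2 0.96, SE 0.15, adjusted p = 0.0413). Without vehicle 2 their adjusted p were 0.246, 0.150, 0.215, 0.150, 0.195 and 0.237. Further large falls were Bmp4, a growth factor (log2 -3.00, SE 0.40, adjusted p = 0.0210), Cdh3, a cadherin (log2 -2.94, SE 0.38, adjusted p = 0.0192), and Coch (log2 -2.78, SE 0.29, adjusted p = 0.00741), at 0.150, 0.144 and 0.0690 without vehicle 2.

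In the cells 111 of 12808 tested genes were called, 17 higher and 94 lower under blebbistatin, of which 7 and 78 changed by at least 2-fold. Leaving out vehicle 1, 2 or 3 gave 321, 13 and 28 calls, and leaving out blebbistatin 1, 2 or 3 gave 27, 25 and 76. Of the 25 called genes named above, 1, 20 and 17 lost their call without vehicle 1, 2 and 3, and 15, 16 and 9 without blebbistatin 1, 2 and 3. Among them Xbp1 and Scd3 passed in the fewest of 25 alternatives, 9 and 10. The 13 genes called with any 1 library left out all fell. They include Krt7 and Ptx3 (log2 -3.47 and -2.24), named after their values were seen. DESeq2 called 134 higher and 350 lower, edgeR's quasi-likelihood test 18 and 97, and the fit on RPKM, the written substitute, 4 and 19. The authors' table calls 454 genes (102 higher, 352 lower), all 111 among them. Of 27 tested lists 16 were called, 4 up and 12 down, and 0 with an estimated correlation (lowest adjusted p = 0.190). Other groupings of these libraries, which mix the treatments, also called 5 to 14 lists in camera at the preset correlation. Fry called 11 in 1 direction and 18 in its mixed test.

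Genes that set the tissues apart were then followed in the cells, among 11599 genes tested in both. Fisher's exact test takes these genes as independent units, which they are not, so its p-values do not measure the spread between libraries. Of 77 genes lower under blebbistatin, 34 were WAT-high genes against 14.1 expected (Fisher's exact test, two-sided, odds ratio 3.58, 95% interval 2.21 to 5.77, adjusted p = 5.26e-07). They include Lep, Ctgf, Timp1, Npr3, Ccl2, Krt19 and Xbp1. Without vehicle 2, which leaves 13 called genes, the odds ratio is 2.98 and adjusted p = 0.372. BAT-high genes made up 14 of the 77 against 13.2 expected (odds ratio 1.07, adjusted p = 1), and the ratio turned to between 0.534 (without vehicle 2) and 0.817 (without blebbistatin 3) whichever library was left out. Of 14 genes higher under blebbistatin 4 were BAT-high (2.40 expected, odds ratio 1.93, adjusted p = 0.561) and 2 WAT-high (2.56 expected, odds ratio 0.746, adjusted p = 1). Without vehicle 1 the BAT-high ratio passed (3.41, adjusted p = 2.02e-04), and it was 3.21 without blebbistatin 3 (adjusted p = 0.413). The WAT-high ratio was 1.57 without vehicle 1, 1.11 without blebbistatin 3 and 0 without blebbistatin 2 (adjusted p = 0.182, 1 and 1). As whole sets, neither the 1992 BAT-high nor the 2117 WAT-high genes were called (median log2 -0.02 and -0.00, camera adjusted p = 0.429 for both, and adjusted p = 0.799 for both with an estimated correlation). The WAT-high set passed without vehicle 1 (adjusted p = 0.0114) and the BAT-high set without vehicle 3 (adjusted p = 0.00796).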

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

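For the muscle transcripts in BAT, the test of brown adipocyte expression was chosen only after the result was seen. Hypothesis: skeletal muscle carried along with the BAT samples may account for part of the sarcomere transcripts. In BAT 4, the library with most of them, muscle markers outside the sarcomere list exceeded the other BAT libraries by a median of 3.43 on the log2 scale (SD 0.859), against 3.58 for the sarcomere list, as that explanation predicted. In the vehicle cells 7 of 32 sarcomere genes reached 1 CPM, between the limits set for and against expression by brown adipocytes, so that test cannot tell. Among the muscle myosins, Myh1 and Myh4 had 0 reads in the vehicle cells and Myh7 had 1, so this cell line did not show them. Neither test separates the lower level in BAT 1 to 3 from expression by the fat cells.

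For the 7991 genes that differ between BAT and WAT, the test of a batch was chosen only after the result was seen. Hypothesis: most of the differences could belong to the tissues, with an unknown part from how the libraries were made. With every library thinned to the shallowest, 5946 genes were still called, so depth alone is excluded as the whole cause. The 2 kinds of library name start in the header share 0 between tissues, which a batch would give and naming by tissue would give too, so batch cannot be told apart. The real grouping gave the most called genes, 1 of 35 splits being as extreme (7991, highest other 0), but 3 of 35 gave as many lists (22, highest other 23), so this count does not exclude chance, though the others that reach it keep 3 libraries of each tissue together and splits with 2 of each call at most 6.

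For Ucp1 under blebbistatin, the tests of a single vehicle library and of a loss of all adipocyte transcripts were chosen only after the result was seen. Hypothesis: Ucp1 may be lower under blebbistatin by an amount these 3 libraries per group measure poorly. Without vehicle 1 the change is -1.78 (SE 0.32) against -2.35, which excludes that library as the sole cause, and the shared adipocyte genes have a median of -0.0746 (SD 0.34, 20 genes), which excludes a loss of all adipocyte transcripts. Thermogenic genes other than Ucp1 stood at a median of 0.32 (SD 0.63) in vehicle 1 over vehicle 3, above 99.95% of random lists but under the limit of 0.5 set for a difference in the whole program, so that test cannot tell.

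In the cells 10 splits cannot give a share under 0.05. The real grouping was the most extreme, 1 of 10, for called genes (111, highest other 0) and for called lists (16, highest other 14). The other groupings, with 0 called genes, still called 5 to 14 lists, so a called list alone does not mark the treatment. For the BAT-high and the WAT-high set 9 of 10 splits gave a p as small (real unadjusted camera p of 0.429 and 0.260, smallest others 1.64e-14 and 4.86e-06).

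Dixon's test at 0.05, on the named genes, the other myosin heavy chains, Rn45s and measures of the libraries within each tissue group, picked 11 values in 224 tests, where 11.2 are expected by chance. Of the genes below, Myh10, Myh11 and Myh13 are outside the naming rule and named after their values were seen. Gpr50 in BAT 4 read 1.30 CPM (others 0). Cpt1b in WAT 3 read 11.3 CPM (others 5.89 to 6.42). Plin4 in BAT 4 read 708 CPM (others 553 to 570). Agt in WAT 2 read 49.6 CPM (others 33.5 to 34.8). Hsd17b7 in BAT 3 read 0 CPM (others 3.91 to 5.53). Tpm2 in BAT 4 read 2899 CPM (others 216 to 307). Gpnmb in BAT 1 read 272 CPM (others 57.8 to 74.8). Edem1 in BAT 4 read 48.2 CPM (others 66.3 to 68.6). Myh13 in WAT 1 read 0.118 CPM (others 0). Myh10 in BAT 4 read 27.3 CPM (others 35.2 to 35.9). Myh11 in WAT 1 read 88.9 CPM (others 22.6 to 26.7).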

How the results depend on the processing

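The settings added after seeing the data are the quasi-likelihood test with TMM (first planned as the main test), no TMM, pseudocounts of 0.1 and 1, thinning and centred RPKM. The others are the cells without 2 ribosomal genes, the cells without vehicle 1 and blebbistatin 3, and, for the gene lists, no filter. Testing every entry of the tables was not run, since each symbol occurs once. Infinite odds ratios, and some from overlaps that held 0 genes, are left out. Residuals of equal replicate numbers correlated across genes at -0.04, -0.00, -0.02 and 0.07 in the tissues and -0.49, 0.32 and -0.26 in the cells. With so few replicates these values cannot tell whether samples of equal number are paired, which remains unknown.

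In the tissues, RPKM gave 773 higher and 9586 lower genes (pseudocount 0.1), 782 and 9788 (pseudocount 1) and 1146 and 10345 (no filter). A 2-fold limit left 4989 genes, 2349 higher and 2640 lower. The quasi-likelihood test gave 4070 and 4022, DESeq2 4949 and 4315, no TMM 3199 and 5024, centred RPKM 4131 and 3618, and thinning 5946 calls. On RPKM with pseudocount 0.1, 744 called genes turned direction, against 2 on RPKM centred on library medians. On centred RPKM 95 named genes kept their direction and their call, or lack of one, and 1 lost its call. Genes named by the rule that turned, with pseudocount 0.1, pseudocount 1, and 0.1 without a filter, were Adipoq (-1.45, -1.44, -1.45), Fabp4 (-0.46, -0.46, -0.46), Yap1 (-0.95, -0.84, -0.95), Cyr61 (-1.08, -1.04, -1.08), Bcar1 (-0.89, -0.67, -0.89), Amotl2 (-0.60, -0.56, -0.60), Tead1 (-0.47, -0.40, -0.47), Ifit1 (-0.00703, -3.82e-04, -0.00703) and Nfkbia (-0.37, -0.36, -0.37). Leaving out 1 library gave 7004 to 8442 genes, 3325 to 3986 higher and 3679 to 4456 lower, 21 to 23 lists, and 9 to 10 myosin genes higher in BAT (11 by CPM). An estimated correlation left 0 lists in the tissues and 0 in the cells.

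In the cells, DESeq2 gave 484 genes (134 higher, 350 lower), the replicate block 30 (0, 30), the quasi-likelihood test with block 27 (0, 27) and without a filter 209 (41, 168). RPKM gave 23 (4, 19) with pseudocount 0.1, 11 (1, 10) with pseudocount 1, 17 (4, 13) without a filter and 54 (7, 47) centred. On RPKM with pseudocount 0.1, 17 of the named genes lost their call. No TMM gave 73 (56 lower), a 2-fold limit 7 higher, and leaving out vehicle 1 and blebbistatin 3 gave 1019 (244, 775). Leaving out 1 library gave 13 to 321 genes, 0 to 54 higher and 13 to 267 lower, and 13 to 19 lists.

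For the overlap, the odds ratio of BAT-high among lower genes was 0.690 with no fold limit, 0.776 with a log2 limit of 2, 0.987 without muscle lists, 0.229 with the block and 0.663 without vehicle 1 and blebbistatin 3. Among higher genes BAT-high had 5.69 (limit of 2) and 1.80 (without those libraries), and WAT-high 1.16 and 1.51. Of these ratios, 5.69 and the 3 without vehicle 1 and blebbistatin 3 (0.663, 1.80 and 1.51) passed the threshold, and the others did not. Without those libraries BAT-high genes were thus fewer than expected among lower genes. Among higher genes both BAT-high and WAT-high genes were then more than expected. That pair of libraries stood apart within its groups and was picked after the data were seen. Leaving it out narrows the spread within groups, so passing in that fit, for a set or a single gene, is no independent support. The adjusted camera p without those libraries were 0.192 for BAT-high and 0.00736 for WAT-high. Leaving out 1 library, adjusted camera p ran from 0.00796 to 0.858 for BAT-high and from 0.0114 to 0.786 for WAT-high. The odds ratios among lower genes ran from 0.534 to 0.817 (BAT-high) and 2.98 to 4.75 (WAT-high). Among higher genes BAT-high had 3.41 without vehicle 1 and 3.21 without blebbistatin 3. WAT-high had 0 to 1.57, the 0 from a fit with 2 higher genes (without blebbistatin 2). Fits without any other library called only 0 to 2 higher genes, so the ratios among higher genes rest on few fits.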

Other observations

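Schwann and nerve markers moved in both directions between the tissues, 3 of 6 higher in BAT, 2 lower and 1 not called, and the list was not called (median log2 1.90, adjusted p = 0.161). S100b, a calcium-binding protein of glia that fat cells also make, rose (2.06 ± 0.672 to 725 ± 79.3 CPM, log2 8.18, SE 0.19, adjusted p = 2.85e-11), while the myelin gene Mbp fell (log2 -0.89, SE 0.14, adjusted p = 1.42e-04). Of 20 genes of the integrated stress response 9 rose, 5 fell and 6 were not called (median log2 0.38, adjusted p = 0.325; median -1.02 on RPKM). Cebpb and Atf5 rose (log2 2.64, SE 0.16, adjusted p = 4.33e-08; log2 1.88, SE 0.14, adjusted p = 2.98e-07, log2 0.45 on RPKM) and Atf3 fell (log2 -3.22, SE 0.21, adjusted p = 8.69e-08). Of 16 p53 targets 5 rose, 6 fell and 5 were not called (median log2 -0.01, adjusted p = 0.949, where the test points up), with Zmat3 and Pmaip1 lower (log2 -2.01, SE 0.17, adjusted p = 5.30e-07; log2 -1.84, SE 0.39, adjusted p = 0.00138) and the death receptor Fas higher (log2 1.80, SE 0.14, adjusted p = 2.76e-07; log2 0.33 on RPKM).

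Interferon genes divided evenly, 5 of 16 higher and 5 lower in BAT with 6 not called (median log2 0.02, adjusted p = 0.823; mean -0.03; median -0.14 without TMM and -1.35 on RPKM). Rsad2 and Ifit1 rose (log2 2.18, SE 0.17, adjusted p = 3.85e-07, log2 0.71 on RPKM; log2 1.41, SE 0.24, adjusted p = 2.19e-04, log2 -0.01 on RPKM) and Oas1a fell (log2 -2.17, SE 0.39, adjusted p = 3.74e-04). Of 13 NRF2 and aryl hydrocarbon receptor targets 2 rose, 6 fell (7 adjusted over the list alone) and 5 were not called (median log2 -0.81, adjusted p = 0.141). Hmox1, which breaks down heme, and Cyp1b1 fell (log2 -2.76, SE 0.19, adjusted p = 1.22e-07; log2 -2.59, SE 0.20, adjusted p = 2.74e-07) and Gsta4 rose (log2 4.51, SE 0.24, adjusted p = 1.58e-08). Epididymis markers, noticed after the data were seen and not tested, summed to 46.1 CPM in WAT 3 (336 reads, with 10 of 12 genes at 1 CPM or more), against 0.706, 0.749 and 2.74 CPM in WAT 1, 2 and 4 and 1.66 to 5.35 CPM in BAT.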
